A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

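The series measured messenger RNA in the budding yeast Saccharomyces cerevisiae, in the laboratory strain BY4741 from the EUROSCARF collection and in cells labelled as its ixr1 null derivative. Ixr1 is a DNA-binding protein with high mobility group boxes, and the series asks about its part in the response to low oxygen. Per the labels' protocols, cells grew at 30 C in synthetic complete medium with 2% glucose under 3 conditions. These were growth in air, overnight growth in anaerobic jars at under 1% oxygen, in medium given ergosterol (20 mg/l) and Tween 80 (0.5%), and a shift in which cultures grown in air to an OD600 of 0.8 were bubbled with nitrogen for 3 hours. Total RNA was primed with oligo-dT, and first-strand cDNA labelled with 32P was hybridised to arrays of yeast open reading frames. The 12 arrays form 6 groups of 2, which the titles letter A and B. The design text speaks of biological replicates measured again as technical replicates. The labels do not say which kind A and B are, so the p-values measure the spread between these arrays, which may be technical.

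The values used here are the intensity values the authors deposited, on a linear scale, with 1 value per open reading frame and array. Each array averages close to 1, every array holds exact zeros, and no value is negative. The scanner, the image software, the background subtraction, the averaging of spots, the scaling and the probe sequences are not given in the sources used here. The table holds 5974 probes. Of their names, 5571 matched a locus tag of the NCBI RefSeq gene table of assembly R64 (GCF_000146045.2), which was used only for gene symbols, and 403 did not and keep the systematic name. No array has the same values as another.

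The tests, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The plan was to keep the deposited scale if the log2 medians of the arrays lay within 0.1 of each other and to quantile normalize otherwise. The medians of the positive values differed by up to 1.49 on the log2 scale, so the 12 arrays were quantile normalized on the linear scale with zeros included. Values of 0 were then set to missing and the others were log2 transformed. Because zeros took the lowest ranks, the dimmest positive values of an array with many zeros were raised, as on ixr1 null shift array A, with 3489. Quantile normalization gives the brightest probe of each array the same value, so a spread of 0 between replicates can arise by construction. A probe was tested in a comparison if it had a value on both arrays of each group involved. A group-means model was fitted over all 12 arrays, which leaves 6 residual degrees of freedom for a probe with no missing value. Variances were moderated as in limma 3.58.1 under R 4.3.3, and the p-values matched those of its lmFit and eBayes functions within 1e-08. Adjusted p-values are Benjamini-Hochberg values over the probes tested in that comparison, and the threshold was 0.05. Folds are on the scale of the normalized intensity, each with the SE of the log2 difference. Arrays carry no counts, so the number of arrays limits the precision. Arrays of the 2 genotypes with the same condition and letter deviated together from their group means, with correlations across probes of 0.257 in air, 0.189 in hypoxia and 0.648 after the shift. For comparisons of genotypes, a fit with a block for the letter within each condition is therefore given where it moves a result. The labels name no batch or day behind the letters, and over the 14 pairs of groups other than the 2 shift groups the correlations ran from -0.06 to 0.30. An exact permutation test of 2 arrays against 2 cannot give a two-sided p under 0.333.

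There were 11 comparisons: each condition against the others in the wild type, each low-oxygen condition against air in the arrays labelled ixr1 null, null against wild type in each condition and averaged over conditions, and the interaction of genotype with overnight hypoxia and with the shift. In all, 35 gene lists were fixed beforehand. Those with at least 4 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. The plan named camera, and because probes have different numbers of values the form that takes moderated statistics (cameraPR) was run in its place. Camera with the correlation estimated per list and fry were run as alternatives. The direction of a list is its direction against the other probes. Counts of list members are given over all probes tested and adjusted over the list alone.

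The text names, in each comparison, the 10 genes that rose most and the 10 that fell most among those past the threshold with replicates that did not overlap. With fewer than 5 past the threshold it names the 5 of smallest p. It also names up to 4 members of each list described, the 2 of smallest p in each direction, and a fixed set of oxygen-responsive, regulatory, mating and deleted genes. Other genes are marked as chosen after their values were seen. Families with near-identical coding sequences, such as the PAU, TDH, HXT and ribosomal protein genes, can cross-hybridise, so the assignment of a signal to a member is uncertain.

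The method was tested on simulated data made from the real mean and pooled spread of each probe, with 50 probes changed at each of 4 sizes. The real differences between groups were not simulated, so the shares recovered below hold for data without them. In the wild type overnight hypoxia comparison, 0% of 2-fold, 16% of 4-fold, 44% of 8-fold and 60% of 16-fold changes were recovered among 4969 probes, with 4 false calls. In the comparison of genotypes in air the shares were 2%, 24%, 52% and 74% among 5043 probes, with 5 false calls. In the interaction with overnight hypoxia they were 0%, 2%, 4% and 24% among 4844 probes, with 0 false calls. Between genotypes after the shift they were 0%, 52%, 70% and 88% among 2231 probes, with 6 false calls. A list raised 2-fold was called in each of 6 simulated comparisons, with 0 other lists called. No correlation between genes was simulated, so this does not test false calls of lists whose members vary together. Replicates of the shift groups differed by a median of 0.987 and 0.923 log2 units, against 0.436 to 0.667 in the other groups. A pooled spread holds neither this nor deviations shared by letter, so the shares after the shift may be too high.

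Alternatives planned beforehand were the deposited values without normalization, centring each array on its median, leaving out the dimmest 25% of probes, using the 2155 probes with a value on all 12 arrays, an offset before the log, a variance prior with an intensity trend, the replicate letter as a block, only the arrays of the groups compared, and leaving out each array in turn. The planned offset, the 10th percentile of all values, came to 0 and changes nothing. Chosen after seeing the data were an offset of 0.0621 (the 10th percentile of the positive values), a floor of 0.114 (the 25th percentile of the normalized values) with zeros kept, quantile normalization of the positive values alone, leaving out probes near the brightest value of the ixr1 null arrays, a block for the letter within each condition, a block for the letter of the shift arrays alone, and leaving out the A or the B shift arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No array or probe was left out of the normalization.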

Results

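Expression was measured on 12 arrays, with 2 arrays in each of 6 groups: wild type cells and cells labelled ixr1 null, each in air, after overnight hypoxia in anaerobic jars, and after a 3 hour shift from air to nitrogen. Each array lists 5974 open reading frames as a radioactive signal scaled to a mean near 1. Of all values 11.8% are exact zeros. They range from 69 probes on wild type shift array B to 3489 on ixr1 null shift array A, and ixr1 null shift array B has 1799. The brightest value was 157 and 201 on the wild type air arrays but 24.5 and 20.8 on the ixr1 null air arrays, where 22 and 25 probes lay within 10% of it against 1 to 5 probes on each of the other arrays. TDH3, for the main glyceraldehyde-3-phosphate dehydrogenase, read 157 and 172 in wild type air and 23.7 and 20.5 in ixr1 null air. At the brightest value itself were 5 probes on ixr1 null air array A, 6 on array B and 3 on ixr1 null hypoxia array B, where 1 was on each other array. Folds of probes at such a ceiling, or with values near 0 in either group, do not fix the size of a change or its rank. In wild type hypoxia against air this holds, among others, for HSP150, PIR3, RPP0, ADH3, ZPS1, YDR360W, TIR1, SKN7 and BAR1. Each read under the 10th percentile of the positive values on at least 1 of those arrays. The same goes for AGA2 in ixr1 null hypoxia, and for CCW12 between the wild type shift and hypoxia. Errors below are SE of log2 differences with n = 2 arrays per group, and all adjusted p-values are from limma.

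Overnight hypoxia arrays stood apart, whereas shift and air arrays did not part cleanly. The rank correlation between replicates, across probes, was 0.917 in wild type hypoxia and between 0.830 and 0.886 in the air groups and ixr1 null hypoxia. It was 0.692 in the wild type shift group and 0.590 in the ixr1 null shift group. In the shift groups the B arrays of the 2 genotypes were closest to each other, at 0.869, and ixr1 null shift array A was closest to wild type shift array A, at 0.719. Wild type shift array A was closest to ixr1 null air array A, at 0.745, and ixr1 null shift array B was as close to that air array (0.869) as to wild type shift array B. Genes of the reserve carbohydrate and stress list, such as HSP12, were a median of 2.33 (wild type) and 2.13 (ixr1 null) log2 units lower on shift array B than on shift array A. The DAN and TIR cell wall mannoprotein genes, markers of low oxygen, were a median of 1.13 (wild type, 7 of 8 measured) and 0.70 (ixr1 null, 3 of 8) higher on B. In the air and hypoxia groups this median ran from -0.21 to 0.40. DAN1 itself was listed at 0 on both shift A arrays and read 2.47 and 7.38 on the B arrays. The wild type air arrays were both closer to ixr1 null air array A (0.846 and 0.879) than to each other.

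**Figure D1:**
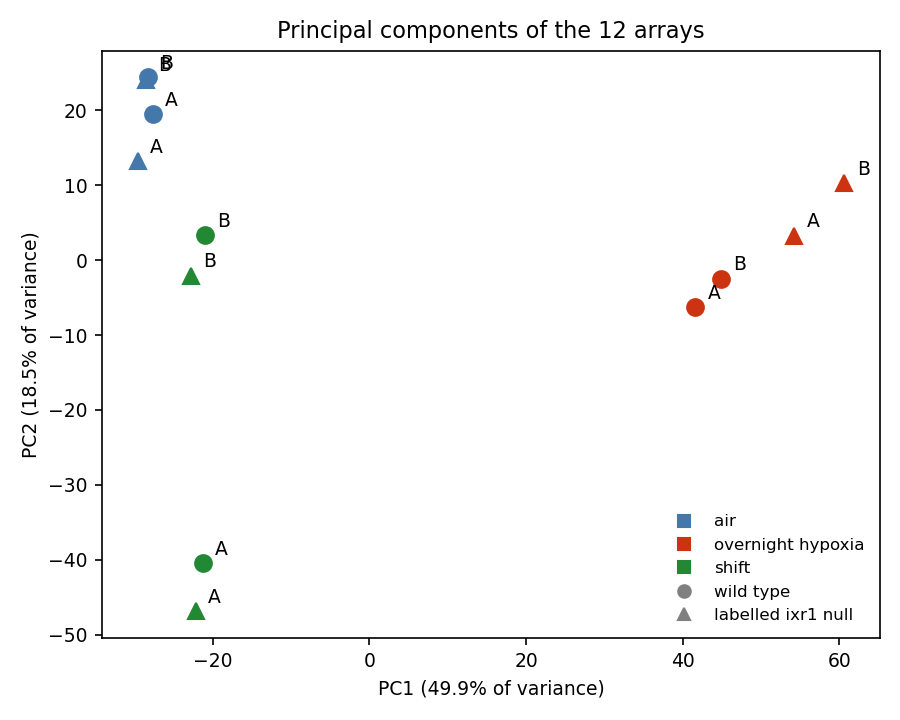
Principal components of the 2155 probes with a value on all 12 arrays, after quantile normalization; each point is an array, coloured by growth condition and shaped by genotype, with its letter. The first component (49.9% of the variance) sets the 4 overnight hypoxia arrays apart, and the second (18.5%) sets the shift A arrays, at -40.5 and -46.9, apart from the shift B arrays, at 3.37 and -2.08.

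The arrays labelled ixr1 null did not show a lower signal for IXR1 itself (YKL032C). In air IXR1 read 8.11 and 7.03 in the wild type and 9.75 and 8.64 in the arrays labelled null, a log2 difference of 0.14 ± 0.48 (adjusted p = 0.997). In hypoxia it read 0.441 and 0.399 against 0.608 and 1.13, a difference of 0.93 ± 0.48 (adjusted p = 0.403), and after the shift 3.60 and 3.01 in the arrays labelled null, a difference of -0.22 ± 0.43 (adjusted p = 0.947). The genes deleted in BY4741 read below IXR1 in air and after the shift, but not always dimly. On ixr1 null air array B, for example, LEU2 read 0.554, above that array's median of 0.392. LEU2, of leucine synthesis, read at most 0.554, MET17, of sulfur assimilation, at most 0.0404, and URA3, of uracil synthesis, at most 0.997 on any array, while HIS3, of histidine synthesis and only partly deleted in this background, read from 0.0645 to 1.44. What part of IXR1 the probe covers is not given in the sources used here, so a probe outside the deleted part cannot be ruled out and the signal neither checks nor contradicts the deletion by itself. The genotype is therefore called as the arrays are labelled throughout, and every direction between genotypes rests on those labels.

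**Figure D2:**
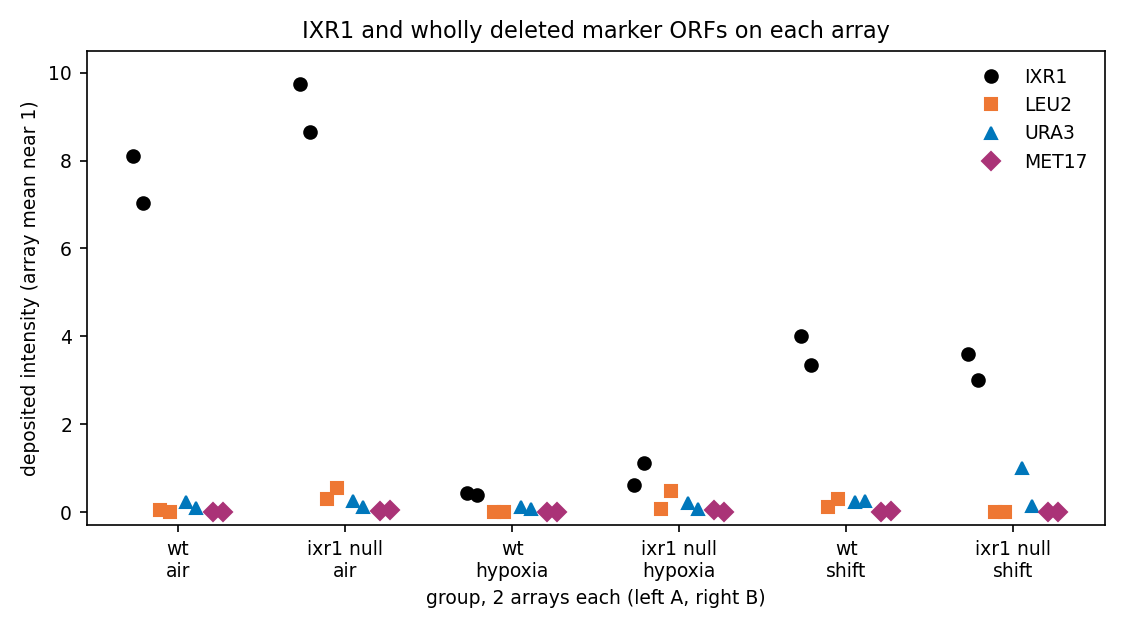
Deposited intensity (y axis) of IXR1 and of LEU2, URA3 and MET17, which are wholly deleted in BY4741, in the 6 groups (x axis); each symbol is an array, A on the left and B on the right. IXR1 lies between 3.01 and 9.75 in air and after the shift in both genotypes, above the 0.997 that is the highest value of LEU2, URA3 or MET17.

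The IXR1 signal itself was lower on the overnight hypoxia arrays of both genotypes. This places IXR1 among the 203 probes, described below, that moved over 16-fold there, for which a different content of the spots on the hypoxia arrays stays open. It fell 22.0-fold in the wild type (log2 difference -4.46 ± 0.48, adjusted p = 0.000266) and 12.7-fold in the arrays labelled ixr1 null (-3.67 ± 0.48, adjusted p = 0.000936). After the 3 hour shift the differences from air were -1.21 ± 0.48 (adjusted p = 0.264) and -1.56 ± 0.43 (adjusted p = 0.109). In the wild type the shift arrays were 9.53-fold above the hypoxia arrays (3.25 ± 0.48, adjusted p = 0.00213).

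The comparison of wild type cells after overnight hypoxia with wild type cells in air addresses the hypoxic programme of normal cells, but oxygen was not all that differed. In both genotypes only the hypoxia medium is described with ergosterol and Tween 80, and these cultures grew overnight in jars. Effects of oxygen cannot be told apart from effects of those. DAN1, a mannoprotein made without oxygen, rose 28.7-fold (4.84 ± 0.80, adjusted p = 0.00465), and among the seripauperins, small stress and anaerobiosis proteins, PAU7 rose 18.6-fold (4.22 ± 0.48) and PAU2 15.9-fold (3.99 ± 0.70). The list of 8 DAN and TIR mannoproteins was not called (median 0.94, 1 rose and 1 fell, also adjusted over the list alone, adjusted p = 0.495). HSP150, a secreted wall mannoprotein, fell 228-fold (-7.83 ± 0.60) and TDH3 fell from the brightest reading of air array A (adjusted p = 2.35e-05), which leaves its fold open. OLE1, the fatty acid desaturase, fell 23.1-fold (-4.53 ± 0.59, adjusted p = 0.000639), in a medium that had been given Tween 80 as a source of unsaturated fatty acids. Of 4969 probes tested, 253 rose and 340 fell. The count of 593 became 365 without air array A, 365 without hypoxia array A and 341 without hypoxia array B, and with zeros kept and values floored 328 rose and 299 fell. The smallest fold that passed was 3.10, and the median of all probes was 0.01 (0.14 on the deposited values). With zeros kept and values floored, DAN1 (4.30, adjusted p = 0.256) and TIR1 (-2.93, adjusted p = 0.441) no longer passed.

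YCF1, for a vacuolar glutathione conjugate pump, rose in the wild type (adjusted p = 2.19e-05) to the brightest probe on each of the 4 hypoxia arrays. YJR018W, YFL067W and SDS3, a subunit of the Rpd3 deacetylase complex, rose to within 10% of the brightest value of wild type hypoxia array B, so no fold is given for these 4. YPR147C rose 263-fold, FMT1, the mitochondrial methionyl-tRNA formyltransferase, 239-fold, ZPS1 192-fold, MTQ2, a release factor methyltransferase, 179-fold and YDR360W 144-fold. Falls besides TDH3 were those of the Ty1 retrotransposon frame YER138C (559-fold), TDH1, the brightest probe on air array B, the aldolase FBA1 (392-fold), the wall protein PIR3 (254-fold), the ribosomal stalk protein RPP0 (235-fold), the alcohol dehydrogenases ADH3 (231-fold) and ADH2 (222-fold) and the Hsp70 chaperone SSA2.

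By gene list, where fry called 8 of 33 lists and shared 5 of the 6 calls of camera given here, the PAU seripauperins were higher (median 1.74, 9 of 20 rose and 0 fell, 13 and 1 adjusted over the list alone, adjusted p = 4.93e-06), with PAU17 at -1.66 and PAU21 at -2.52 among those that did not pass. Aerobic cell wall genes were lower (median -2.98, 9 of 18 fell and 0 rose, 10 and 0 adjusted over the list alone, adjusted p = 1.79e-08), including BGL2, a wall glucanase, by 103-fold. SPI1 (2.28) and UTR2 (1.61) were above air without passing. Glycolysis and fermentation genes were lower (median -1.48, 13 of 29 fell and 0 rose, 14 and 1 adjusted over the list alone, adjusted p = 6.97e-08), yet ADH4 (1.94) and the isomerase TPI1 (0.39) did not follow. Amino acid synthesis genes were lower (median -0.90, 16 of 46 fell and 0 rose, 18 and 0 adjusted over the list alone, adjusted p = 4.22e-07), among them ILV6, of branched-chain synthesis, by 39.2-fold and ARO4, of aromatic synthesis, by 17.5-fold. Sulfur and methionine genes were lower as well (median -0.79, 9 of 27 fell and 0 rose, 9 fell and 2 rose adjusted over the list alone, adjusted p = 0.000765, adjusted p = 0.109 with an estimated correlation), led by SAM1, an S-adenosylmethionine synthetase, at 180.3-fold and MHT1 at 24.3-fold. Mitochondrial ribosomal protein genes were slightly higher (median 0.42, 8 of 71 rose and 2 fell, with the same counts adjusted over the list alone, adjusted p = 0.0171, adjusted p = 0.075 with an estimated correlation). MRPL8 (31.1-fold) and MRPS5 (21.2-fold) rose and MRP51 (13.5-fold) and MRPL35 (3.67-fold) fell.

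The list of hypoxic genes, many of them repressed by Rox1 in air, was not called in the same comparison, with members going both ways. Of the 21 tested, DAN1 rose and 4 fell, also when adjusted over the list alone (median -0.14, adjusted p = 0.737). ANB1, the hypoxic form of translation factor eIF5A, differed by 0.05 ± 0.51, HEM13, of heme synthesis, by -0.18 ± 0.48, COX5B, a hypoxic cytochrome oxidase subunit, by 0.99 ± 0.65, CYC7 by 0.73 ± 0.47, CYC1 by -1.12 ± 0.59 and ROX1, the repressor, by -0.63 ± 0.42, all with adjusted p between 0.331 and 0.976. HYP2, the other eIF5A gene, read 2.46 and 3.58 in wild type air and 2.31 and 3.35 in hypoxia, close to ANB1 at 2.38 and 3.30, and 2.22 and 3.98. A signal shared by these probes is not excluded, so the ANB1 value does not show that ANB1 itself was unchanged. AAC3, the anaerobic ADP/ATP carrier, was listed at 0 on all 4 air arrays and read 0.267 and 0.347 in wild type hypoxia. TIR1, a mannoprotein also made in the cold and without oxygen, fell 20.0-fold (-4.32 ± 0.67, adjusted p = 0.00235), while TIR2 was at 2.99 (adjusted p = 0.125). ADH5 fell 32.0-fold. In the ergosterol pathway, in a medium that held ergosterol, ERG28 rose 3.42-fold and 5 of 24 genes fell, ERG1 by 12.7-fold, ERG4 (-2.91 ± 0.61) and ERG11, the sterol demethylase, by 7.05-fold (-2.82 ± 0.76, adjusted p = 0.0364). The list as a whole was not called (median 0.28, adjusted p = 0.869), and ERG11 lost its call on the deposited values (adjusted p = 0.0848) and with arrays centred on their medians (adjusted p = 0.12). Respiratory chain genes (median 0.01, 1 of 26 rose, adjusted p = 0.497) were not called either.

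Regulators and mating genes were also examined. Among 20 regulators of oxygen-responsive genes, IXR1, SKN7, of the oxidative stress response (22.5-fold, -4.49 ± 0.74, adjusted p = 0.00327) and HAP2, of the respiratory activator complex (5.99-fold, -2.58 ± 0.59, adjusted p = 0.0157) fell, and 0 rose. Of the a-specific mating genes, BAR1, the pheromone protease, fell 29.1-fold, MFA2, an a-factor gene, 85.0-fold and AGA2, of the agglutinin, by 3.33 ± 0.47 log2 units, whereas ASG7 rose 4.58-fold. The MFA2 call was lost in 8 of 15 alternatives and the ASG7 call in 7 of 15. The alpha-specific MF(ALPHA)1 and SAG1 differed by 0.19 ± 1.14 and 0.55 ± 0.55.

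After the 3 hour shift to nitrogen, the stress genes TSA2 and SIP18 rose in wild type cells. TSA2, a thioredoxin peroxidase, rose 13.9-fold (3.80 ± 0.54, adjusted p = 0.0101). SIP18, a desiccation and osmotic stress protein, rose (adjusted p = 0.0115) from air readings of 0.0581 and 0.0341, under the 10th percentile of the positive values. No fold is given for SIP18. Its log2 difference ran from 5.31 to 7.36 over the alternatives, with the call lost in 4 of 19. Glycolytic and wall genes fell. FBA1 and CCW12, an abundant wall mannoprotein, fell to shift readings under the 10th percentile of the positive values on at least 1 array. Over the alternatives their log2 differences ran from -12.90 to -9.05 and from -11.71 to -9.15. TDH1, TDH2 and TDH3 fell from readings at or near the brightest value of an air array. No fold is given for any of these genes. YJR018W (360.4-fold), YFL067W, YPR147C (245-fold), FMT1 (188-fold) and the nucleolar NET1, with 7.12 ± 0.92, also rose. YCF1, SDS3 and VEL1 rose from air readings under the 10th percentile of the positive values on at least 1 array, so no fold is given. ADH5 (30.7-fold) and XKS1 (27.8-fold) fell. YER138C, LEU1 and YAR068W fell to shift readings under that percentile on at least 1 array, again without a fold. Of 4672 probes 15 rose and 20 fell, 739 had an unadjusted p under 0.05, and the median was 0.04 (-0.08 on the deposited values). With a block for the letter of the shift arrays alone, chosen after seeing the data, 191 rose and 227 fell. That block takes the A to B difference that the shift groups share out of the error. The wild type air arrays shared little of it (correlation across probes 0.066), so the blocked counts leave out part of the spread between shift replicates. The planned count, without the block, was 35. The count depends on the arrays used: 90 without wild type shift array A, 333 without shift array B, 12 without wild type air array A, 13 without air array B, 123 without the shift A arrays of both genotypes and 699 without the shift B arrays of both.

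By gene list, camera called 8 of 31 lists after the shift, of which fry called 1, glycolysis, and 5 held with an estimated correlation. Glycolysis and fermentation genes were lower (median -1.29, 25 of 28 lower, 5 fell and 0 rose, 11 and 0 adjusted over the list alone, adjusted p = 3.66e-10), and aerobic cell wall genes were lower (median -1.69, 2 of 17 fell, 8 adjusted over the list alone, adjusted p = 1.34e-05), GAS1, a wall glucanosyltransferase, by 3.81 ± 0.63 log2 units. The PAU genes were above air for 20 of 20 members (median 1.13, adjusted p = 1.34e-05), yet 0 passed the gene test in limma and 5 rose adjusted over the list alone, with PAU2 at 3.19 ± 0.70 (adjusted p = 0.0744). Ribosome biogenesis genes were lower as a list (median -0.78, 0 of 60 past the gene test or adjusted over the list alone, adjusted p = 7.19e-05), with NOP15 at -2.60 and ERB1 at -2.70, and so were amino acid synthesis genes (median -0.57, 1 of 46 fell, 3 adjusted over the list alone, adjusted p = 0.00247), where LEU1 fell and ILV6 stood at -1.94. Cytosolic ribosomal protein genes were higher (median 0.48, 1 of 114 rose, also adjusted over the list alone, adjusted p = 0.00985, adjusted p = 0.587 with an estimated correlation), RPL29 by 13.2-fold. The RPL29 call was lost in 9 of 19 alternatives and the GAS1 call in 7 of 18. Mitochondrial ribosomal genes (median 0.34, 0 of 69 past the gene test, 2 rose adjusted over the list alone, adjusted p = 0.0228, adjusted p = 0.0844 with an estimated correlation), led by MRPL37 at 2.15, and reserve carbohydrate and stress genes (median 0.56, 1 of 31 rose, 3 adjusted over the list alone, adjusted p = 0.0401, adjusted p = 0.586 with an estimated correlation) were higher. HSP12 stood at 3.31 ± 0.79 (adjusted p = 0.104), and without the shift A arrays the median of this last list was -0.30. The mitochondrial ribosome call was lost on the deposited values (median 0.33), with arrays centred on their medians (0.51) and with quantile normalization of positive values only (0.40). Hypoxic genes were not called (median -0.05, adjusted p = 0.679). CYC7 was at 1.87 ± 0.46 (adjusted p = 0.117), ROX1 at -1.60 ± 0.41 (adjusted p = 0.118) and HEM13 at 0.52 ± 0.48 (adjusted p = 0.617).

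Set against overnight hypoxia, the ribosomal protein gene RPL25 was 79.0-fold higher in the wild type shift arrays (6.30 ± 0.96) and OLE1 17.7-fold (4.15 ± 0.59, adjusted p = 0.00188). RPP0 (adjusted p = 0.000409), MET16, of sulfate assimilation, and TIR1 (adjusted p = 0.0199) were higher too. Their hypoxia readings lay under the 10th percentile of the positive values on at least 1 array, so no fold is given. YKR040C (127-fold), EGD1, a nascent chain factor (122-fold), and GRE1 (81.2-fold) rose too. IPL1, the Aurora kinase, DAD2, of the kinetochore, ATG10, of autophagy, and PRB1, the vacuolar proteinase B, rose from hypoxia readings as low as those, without a fold. NFG1 (112-fold), YDL026W (89.9-fold), MTQ2 (82.9-fold) and YDR112W (-6.27 ± 0.59) were lower after the shift. So were NSA1, of ribosome assembly, RFA1, of replication protein A, YOL035C, YDL163W, SMC3, of cohesin, and MAD3, of the spindle checkpoint. Their shift readings lay under the 10th percentile of the positive values on at least 1 array, so no fold is given. NSA1 ran from -12.29 to -4.66 log2 units over the alternatives, with its call lost in 3 of 18. BAR1, AGA2 (5.09-fold) and SKN7 were higher and ASG7 (6.09-fold) lower. BAR1 and SKN7 read under the 10th percentile of the positive values on hypoxia array B, so no fold is given. SKN7 ran from 1.36 to 4.54 log2 units over the alternatives. Its call was lost in 6 of 18, that of TIR1 in 6 of 18, ASG7 in 5 of 18, AGA2 in 4 of 18 and BAR1 in 1 of 18.

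Of 4893 probes in this comparison, 259 rose and 183 fell, with a median of 0.04 (-0.21 on the deposited values). The count was 191 without wild type hypoxia array A and 196 without hypoxia array B. The balance turned without wild type shift array A (236 rose and 337 fell), without shift array B (261 and 333), without the shift A arrays of both genotypes (273 and 398) or the shift B arrays of both (372 and 467), and with zeros kept and values floored (217 and 276). Camera called 4 of 33 lists, and fry called 1, none of those 4. Cytosolic ribosomal protein genes were higher (median 0.70, 11 of 115 rose and 2 fell, 13 and 2 adjusted over the list alone, adjusted p = 2.79e-05, adjusted p = 0.565 with an estimated correlation), RPL27A by 29.4-fold, while RPL4A (7.09-fold) and RPS8B (31.3-fold) fell. Sulfur genes were higher (median 1.04, 10 of 27 rose and 1 fell, 12 and 1 adjusted over the list alone, adjusted p = 3.73e-05, adjusted p = 0.0697 with an estimated correlation), MET14, adenylylsulfate kinase, by 54.6-fold and MHT1 by 50.5-fold, with the methionine permease MUP3 down 16.4-fold. Aerobic wall genes were higher (median 0.87, 7 of 17 rose and 1 fell, 8 and 2 adjusted over the list alone, adjusted p = 0.00176), TIP1 by 50.3-fold and SED1 by 21.7-fold against CCW12, which fell 10.1-fold. Amino acid synthesis genes were higher (median 0.49, 0.25 on the deposited values, 13 of 45 rose and 0 fell, the same adjusted over the list alone, adjusted p = 0.00729, adjusted p = 0.104 with an estimated correlation), ARO4 by 19.4-fold and LEU4 by 22.5-fold.

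In the arrays labelled ixr1 null, DAN1 rose 49.2-fold in overnight hypoxia (5.62 ± 0.82, adjusted p = 0.00376), PAU7 39.0-fold (5.28 ± 0.48) and PAU3 14.1-fold (3.82 ± 0.70). TIR1 fell 17.8-fold (-4.16 ± 0.68), HSP150 119-fold (-6.90 ± 0.61) and MET14 236-fold (-7.88 ± 0.53). MFA2 fell too, from 14.6 and 11.2 to 0.0439 and 0.000543, too near 0 to fix a fold. OLE1 was at -1.32 ± 0.60 (adjusted p = 0.219), HEM13 at -1.25 ± 0.48 (adjusted p = 0.145) and ANB1 at -0.08 ± 0.51. YJR018W rose as well, to 56.7 and 49.9 from 0.0264 and 0.0302, as did YFL067W. Both lay at or near the ceiling of the hypoxia arrays, so no fold is given. SOA1 rose 401-fold. Other rises were those of YPR147C, FMT1, NSA1, the nucleoporin NUP60, YDL041W, RFA1 and the ribosomal gene RPL35B. YKR040C and TDH1 fell from readings at or near the ceiling of the air arrays (24.5 and 20.4, and 24.2 and 20.8), which leaves their folds open. Other falls were those of YET1, TRX2, a thioredoxin, AIR2, of the nuclear RNA surveillance complex, ENV9, ABP140, YOR338W and ANT1. These rises began and these falls ended, on at least 1 array, under the 10th percentile of its positive values, so no fold is given. With zeros kept and values floored, the rises ran from 4.32 (RPL35B) to 8.95 (YPR147C) and the falls from -5.22 (TRX2) to -6.14 (AIR2), and ANT1 lost its call. ABF2, the mitochondrial HMG-box protein, fell 4.09-fold (adjusted p = 0.0484), a call that was lost in 9 of 16 alternatives.

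Of 5505 probes, 353 rose and 307 fell. The median of all probes was -0.20, against -0.03 on the deposited values and -0.12 with arrays centred on their medians, so changes are relative to that shift, and 427 and 402 probes passed under those scalings. Without ixr1 null air array A the count was 389, without ixr1 null hypoxia array A 234 rose and 285 fell, and without hypoxia array B 212 rose and 280 fell. Camera called 6 of 33 lists and fry 8, with 5 shared. The PAU list was higher (median 1.81, 8 of 20 rose and 0 fell, 12 and 1 adjusted over the list alone, adjusted p = 3.66e-06). Wall genes were lower (median -1.40, 8 of 18 fell, the same adjusted over the list alone, adjusted p = 0.000696), among them CWP2, which sat near the ceiling of air array A. Sulfur genes were lower (median -1.95, 10 of 25 fell and 2 rose, 15 and 2 adjusted over the list alone, adjusted p = 9.75e-05, adjusted p = 0.0571 with an estimated correlation), MET5, a sulfite reductase subunit, by 66.3-fold, while MET8 (5.80-fold) and MUP3 (13.7-fold) rose. Oxidative stress genes were lower (median -0.76, -0.49 on the deposited values, 7 of 35 fell and 1 rose, 10 and 1 adjusted over the list alone, adjusted p = 0.0286, adjusted p = 0.257 with an estimated correlation), GRX1 by 38.6-fold, with the peroxidase GPX2 up 8.25-fold. Cytosolic ribosomal genes were lower (median -0.54, 10 of 120 fell and 3 rose, the same adjusted over the list alone, adjusted p = 0.0286, adjusted p = 0.756 with an estimated correlation), with RPL27A down 62.4-fold and RPL4A up 29.0-fold. The a-specific mating genes were lower (median -1.41, 2 of 5 fell, the same adjusted over the list alone, adjusted p = 0.0286, adjusted p = 0.172 with an estimated correlation), AGA2 by 49.7-fold. Glycolysis genes, whose values crowded below a ceiling on the air arrays of this genotype, were not called (median -0.68, 9 of 29 fell and 1 rose, 11 and 3 adjusted over the list alone, adjusted p = 0.0869).

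The hypoxia responses of the genotypes shared many genes. Among the 4844 probes tested in both, 140 rose in both, where 14.5 would be shared by chance if the calls were independent. Likewise 170 fell in both, where 19.4 would be. The differences rest on separate arrays, but both tests use the same error estimate for a probe and arrays normalized together. The calls are therefore not independent, and these chance numbers may be too low. The single gene called in opposite directions was not examined further. Across probes, which are not independent replicates, Pearson's r was 0.65 and Spearman's rho 0.42.

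**Figure D3:**
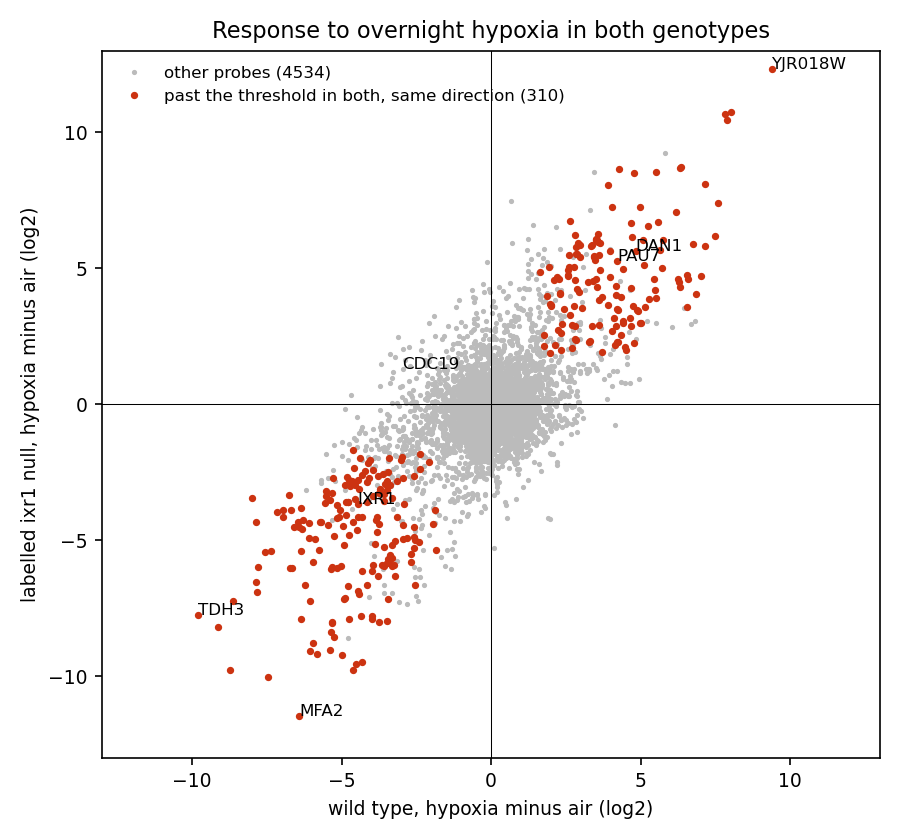
Log2 difference between overnight hypoxia and air in the wild type (x axis) and in the arrays labelled ixr1 null (y axis) for 4844 probes; coloured points passed the test in both genotypes in the same direction (310 probes), and named genes include DAN1, PAU7, TDH3, MFA2, IXR1, CDC19 and YJR018W. Most coloured points lie near the diagonal, with DAN1 at 4.84 and 5.62 and CDC19 off it at -2.96 and 1.31.

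After the shift the arrays labelled ixr1 null could be compared with air for 2228 probes, because only 2250 probes had a value on both shift arrays. Shift array A listed 3489 probes at 0 and array B 1799. Among probes with signal on both air arrays, 1288 were at 0 on both shift arrays. YJR018W rose (adjusted p = 3.9e-06) from air readings of 0.0264 and 0.0302, under the 10th percentile of the positive values, to near the ceiling of shift array B. No fold is given, and its log2 difference ran from 9.63 to 12.55 over the alternatives. FMT1, YPR147C, YFL067W and NET1 rose as well, with a lowest log2 difference over the alternatives of 8.73, 8.76, 9.09 and 6.63. FMP45, ILV3, of branched-chain amino acid synthesis, YCG1, of condensin, MST1 and SCM3 rose, from air readings under the 10th percentile of the positive values on at least 1 array, so no fold is given. The call was lost in 10 of 17 alternatives for FMP45 (log2 1.81 to 8.49), 9 of 19 for ILV3 (3.57 to 7.87), 12 of 19 for MST1 (3.56 to 6.74) and 9 of 18 for SCM3 (1.78 to 6.18). YCG1 kept its call in all 19 (2.42 to 5.73). TDH2 fell (adjusted p = 0.0139) from readings exactly at the ceiling of the air arrays, which leaves its fold open. YER138C fell 56.8-fold, with its call lost in 3 of 19 alternatives, and YOL106W 5.25-fold, lost in 11 of 19 (-3.61 to -1.99). Because the zeros of shift array A took the lowest ranks, normalization raised its dimmest positive values. YER138C went from 0.139 to 0.474 there, and ABP140 from 0.0107 to 0.376. This shrinks falls to dim readings, that of YER138C included, and probes at 0 on a shift array were not tested. In all 41 rose and 3 fell, at a median of 0.30. On the deposited values 8 rose and 17 fell (median -0.29), with 10 of those calls shared, and with arrays centred on their medians 6 rose and 22 fell (median -0.78). With quantile normalization of positive values only 6 rose and 21 fell (median -0.82), so the balance of directions followed the scaling. The count was 8 without air array A, 14 without air array B, 11 without shift array A and 126 without shift array B. Of 28 lists tested with limma's camera 0 were called, 0 with an estimated correlation and 0 by fry, and 322 probes had an unadjusted p under 0.05. PAU14 (5.74-fold) and PAU7 (4.23-fold) rose within a list at a median of 0.83 (2 of 13 rose, also adjusted over the list alone, adjusted p = 0.198).

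Genotypes in air differed in no gene past the threshold. The smallest p-values belonged to TPO4, a polyamine exporter (-3.05 ± 0.48, adjusted p = 0.261), PRM7, a pheromone-regulated gene (-4.06 ± 0.62), DEP1, of the Rpd3 complex (-3.29 ± 0.50), EEB1, an ethyl ester synthase (-2.74 ± 0.47) and DIC1, the mitochondrial dicarboxylate carrier (-2.54 ± 0.47), each with an adjusted p up to 0.267. Of 5043 probes 0 passed in limma and 382 had an unadjusted p under 0.05, at a median of 0.08, against 0.39 on the deposited values and 0.21 with quantile normalization of positive values only. With zeros kept and values floored, 3 fell. With a block for the array letter within each condition 0 passed in limma, with 754 at an unadjusted p under 0.05.

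Camera called 10 of 32 lists between genotypes in air, each with 0 members past the gene test in limma. Of them fry called 2, sulfur and iron. Amino acid synthesis genes were lower in the arrays labelled ixr1 null (median -0.73, 42 of 49 lower, adjusted p = 1.79e-05), with ILV3 at -4.40 and LYS20 at -1.52. Ribosome biogenesis genes were lower (median -0.51, 49 of 72, adjusted p = 0.00127), with ENP1 at -1.60 and NOP14 at -1.64. Glycolysis genes were lower (median -0.46, 24 of 29, adjusted p = 0.00259), with the pyruvate kinase gene CDC19 at -1.60 and ADH5 at -2.23, on air arrays whose values crowded below a ceiling. Mitochondrial ribosomal genes were higher (median 0.50, 51 of 71, adjusted p = 0.00517), with RSM24 at 2.04. Adjusted over the list alone, 0 members of these lists passed. Sulfur genes were higher (median 0.54, 2 rose adjusted over the list alone, adjusted p = 0.00244, adjusted p = 0.109 with an estimated correlation), with MET14 at 2.11 and MET5 at 1.98. Reserve carbohydrate and stress genes were higher (median 0.54, 2 rose adjusted over the list alone, adjusted p = 0.00517, adjusted p = 0.538 with an estimated correlation), with SIP18 at 3.88. HSP12, at 3.27, sat near the ceiling of the ixr1 null air arrays. On the deposited values the medians were -0.43 for amino acid synthesis, -0.12 for ribosome biogenesis, 0.78 for mitochondrial ribosomal genes and 0.82 for reserve carbohydrate genes, whose call was lost there (adjusted p = 0.0795). With arrays centred on their medians the glycolysis median was -0.70.

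Also called in air were the iron regulon (median -0.50, -0.18 on the deposited values, 2 of 23 fell adjusted over the list alone, adjusted p = 0.0253, adjusted p = 0.101 with an estimated correlation), with the siderophore genes ARN2 at -2.51 and FIT3 at -2.45. Wall genes (median -0.54, 0 adjusted over the list alone, adjusted p = 0.026, adjusted p = 0.0719 with an estimated correlation) included BGL2 at -1.19. Hexose transporter genes (median -1.03, 1 of 14 fell adjusted over the list alone, adjusted p = 0.0451, adjusted p = 0.143 with an estimated correlation) included HXT1 at -1.73. The DAN and TIR genes were above the wild type for 8 of 8 members (median 0.74, 0 adjusted over the list alone, adjusted p = 0.0451, adjusted p = 0.0974 with an estimated correlation), with TIR4 at 1.65. Hexose transporter and DAN and TIR calls were lost on the deposited values (medians -0.53 and 0.99), with arrays centred on their medians (-0.75 and 0.77) and with quantile normalization of positive values only (-0.71 and 0.81).

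In overnight hypoxia, 15 genes differed between the genotypes. TIP1, a cell wall mannoprotein, was 22.4-fold higher in the arrays labelled ixr1 null (4.48 ± 0.67, adjusted p = 0.0405) and CDC19, which makes pyruvate in the last step of glycolysis, 6.37-fold higher (2.67 ± 0.44, adjusted p = 0.0493). AIR2 was 27.1-fold lower (-4.76 ± 0.48, adjusted p = 0.00947), TRX2 20.2-fold lower (-4.33 ± 0.65, adjusted p = 0.0405) and MRPL8, of the mitochondrial ribosome, 12.7-fold lower (-3.66 ± 0.53, adjusted p = 0.0405). HSL7, of the morphogenesis checkpoint (26.0-fold), YAR069C (23.0-fold), SPP381, a splicing factor (12.1-fold), NTG1, a DNA glycosylase (10.3-fold), SDS23 (8.32-fold) and AAD3 (2.81 ± 0.44) were also higher. YET1 (20.8-fold), VMA8, of the vacuolar ATPase (12.2-fold), MIC19, of the mitochondrial inner membrane (11.7-fold) and YRB1, a Ran-binding protein (9.87-fold), were lower. With zeros kept and values floored, TRX2 stood at -0.04, YET1 at -0.22 and MIC19 at -0.19, each without its call, while AIR2 at -1.41, YRB1 at -1.69 and HSL7 at 2.12 kept theirs. Each of the 15 genes lost its call in 5 to 12 of the 16 or 17 alternatives run on it. None of the 24 hypoxic genes passed in limma: OLE1 at 1.32 ± 0.60, AAC3 at 1.90 ± 0.84, HEM13 at -0.62 ± 0.48 and ROX1 at 0.16 ± 0.42, with adjusted p between 0.349 and 0.895.

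Of 5379 probes, 8 rose and 7 fell in this comparison and 771 had an unadjusted p under 0.05, at a median of -0.16. On the deposited values (median 0.21) and with arrays centred on their medians (median -0.04), 1 rose and 0 fell under each, as with quantile normalization of positive values only (median -0.01). Without wild type hypoxia array A or B the count was 0, without ixr1 null hypoxia array A it was 24 (4 rose and 20 fell) and without array B it was 1. With a block for the array letter within each condition 0 rose and 1 fell.

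The glycolysis, amino acid, hexose transporter, wall, mitochondrial ribosome and sulfur lists each ran opposite to air. Camera called 10 of 34 lists in hypoxia and fry 0. Glycolysis genes were higher in the arrays labelled ixr1 null (median 0.85, 22 of 29 higher, 1 rose, also adjusted over the list alone, adjusted p = 0.000757), with the mutase GPM1 at 1.98. Amino acid synthesis genes were higher (median 0.57, 35 of 46, 0 adjusted over the list alone, adjusted p = 0.00215), with HIS4 at 1.41. Hexose transporter genes were higher (median 1.07, 13 of 16, 2 rose adjusted over the list alone, adjusted p = 0.0036), with HXT2 at 3.09 and HXT3 at 2.24. Wall genes (median 0.72, 1 of 18 rose, 2 adjusted over the list alone, adjusted p = 0.00685) and citric acid cycle genes (median 0.58, 0 of 23 rose, also adjusted over the list alone, adjusted p = 0.0153), with ICL1 at 1.85, were higher. The citric acid cycle call was lost on the deposited values (median 0.73) and with arrays centred on their medians (0.49). Mitochondrial ribosomal genes were lower (median -0.69, 55 of 72, 1 fell, also adjusted over the list alone, adjusted p = 0.00685), and so were a-specific mating genes (median -1.35, 5 of 5 lower, 2 fell adjusted over the list alone, adjusted p = 0.00626), with AGA2 at -2.18 and MFA2 at -5.03. Both read under the 10th percentile of the positive values on the ixr1 null hypoxia arrays, so the size of these 2 differences is not fixed. Sulfur genes (median -1.18, 3 of 24 fell and 1 rose adjusted over the list alone, adjusted p = 0.0265, adjusted p = 0.255 with an estimated correlation), with MET5 at -2.72, and ATP synthase genes (median -0.74, 1 of 14 fell adjusted over the list alone, adjusted p = 0.0438, adjusted p = 0.172 with an estimated correlation and 0.0517 with the block by letter), with INH1 at -2.36, were lower. PAU genes were slightly higher (median 0.24, 0 of 20 rose, also adjusted over the list alone, adjusted p = 0.0438, adjusted p = 0.255 with an estimated correlation), a call lost on the deposited values (median 0.20), with arrays centred on their medians (-0.04) and with quantile normalization of positive values only (0.28). On the deposited values the medians were 0.85 for amino acid synthesis, -0.17 for mitochondrial ribosomal and -0.37 for ATP synthase genes.

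**Figure D4:**
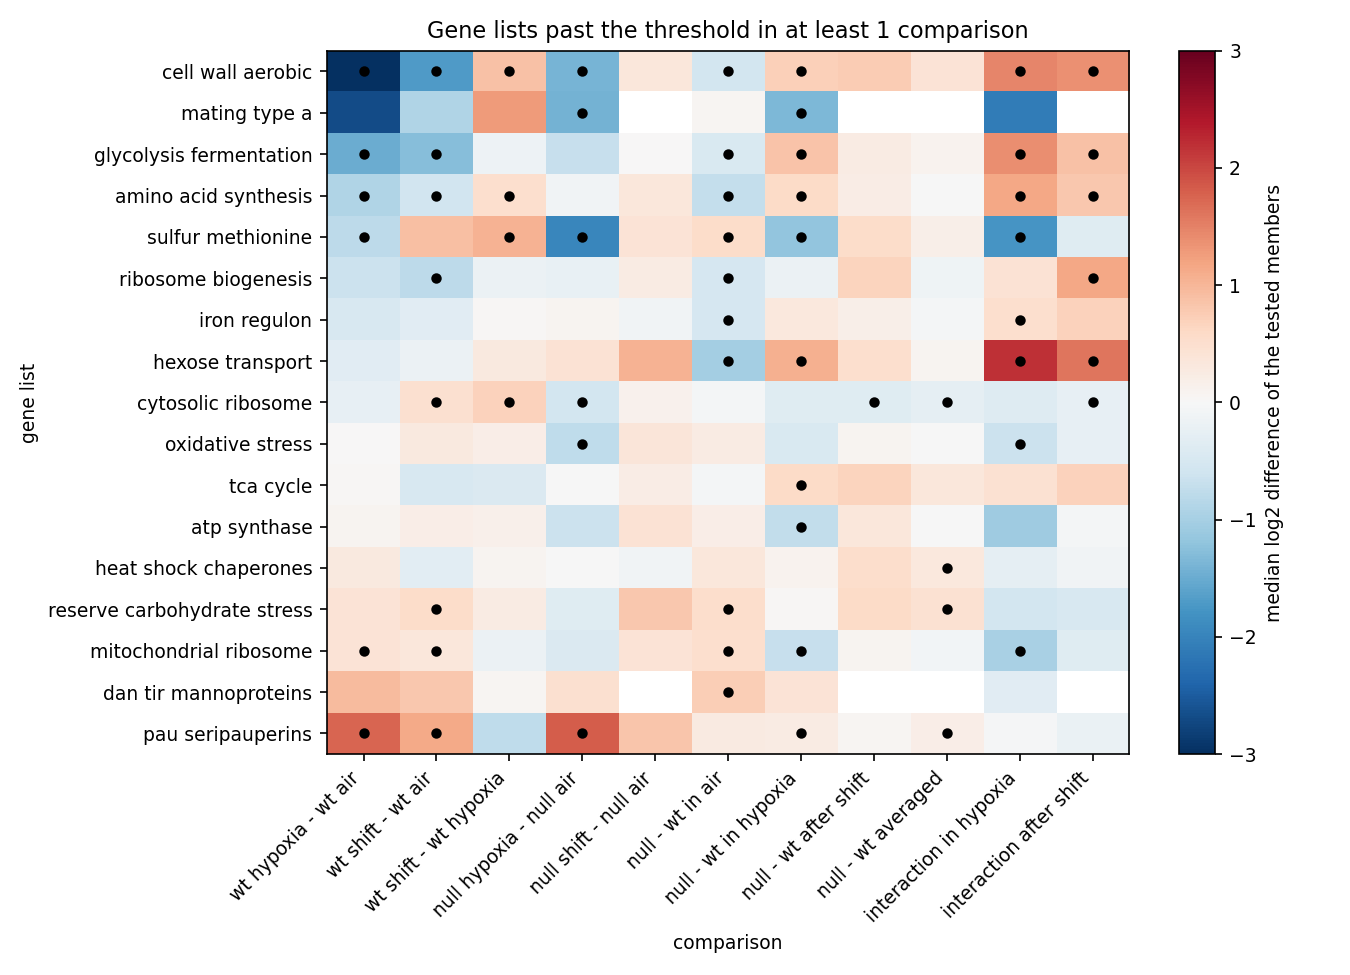
Median log2 difference of 17 gene lists (rows) in the 11 comparisons (columns), on a colour scale from -3 to 3, where a dot marks a list past the camera test (63 dots) and white marks fewer than 4 tested members. Cell wall, glycolysis and amino acid lists are low in wild type hypoxia (-2.98, -1.48 and -0.90), and between genotypes their medians are below 0 in air and above 0 in hypoxia.

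After the shift no gene separated the genotypes past the threshold in the fit without a term for the array letter, although the shift arrays differed by letter. ADE1, of purine synthesis, stood at 2.67 ± 0.42 and YDR340W at -2.56 ± 0.42, both with adjusted p = 0.123, followed by RPL29 at -3.66 ± 0.68, EBP2, of ribosome assembly, at 3.30 ± 0.64 and YGL069C at 2.39 ± 0.50. Of 2231 probes 0 passed in limma and 170 had an unadjusted p under 0.05, at a median of 0.16 that became -0.13 on the deposited values, -0.90 with quantile normalization of positive values only and -1.02 with arrays centred on their medians, where 13 fell. Without wild type shift array A 14 passed and without ixr1 null shift array B 13 passed. Without both shift A arrays 18 passed and without both shift B arrays 21. With a block for the array letter within each condition 19 rose and 1 fell. Cytosolic ribosomal genes were lower (median -0.36, 0 of 102 past the gene test, 1 fell adjusted over the list alone, adjusted p = 6.67e-08, adjusted p = 0.424 with an estimated correlation), while fry called 0 of 28 lists, and without ixr1 null shift array A their median was 0.22. The call was lost on the deposited values (median -0.45), with arrays centred on their medians (-1.34) and with quantile normalization of positive values only (-1.21).

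Averaged over the conditions, AAD3, an aryl alcohol dehydrogenase homolog, was 2.81-fold higher in the arrays labelled ixr1 null (1.49 ± 0.23), YDR340W was 3.22-fold lower (-1.69 ± 0.24) and FPK1, a kinase of lipid flippases, 3.15-fold lower (-1.65 ± 0.25), each with adjusted p = 0.0379 and n = 6 arrays per genotype. AIR2 followed at -1.39 ± 0.25 (adjusted p = 0.116) and MET8 at 1.25 ± 0.23 (adjusted p = 0.125). These 3 of 2155 probes passed (174 at an unadjusted p under 0.05, median -0.02). The count was 0 on the deposited values (median 0.03), 0 with arrays centred on their medians (median -0.43), 0 with quantile normalization of positive values only (median -0.32), 0 without any of the other 10 arrays, and 1 without wild type shift array B or without ixr1 null shift array B. With a block for the array letter within each condition 5 rose and 3 fell. Cytosolic ribosomal genes were lower (median -0.26, 82 of 101 lower, 0 adjusted over the list alone, adjusted p = 7.65e-05, adjusted p = 0.518 with an estimated correlation). Reserve carbohydrate genes were higher (median 0.46, 18 of 20 higher, 0 adjusted over the list alone, adjusted p = 0.00204, adjusted p = 0.376 with an estimated correlation), with GSY2, glycogen synthase, at 0.89. Heat shock genes (median 0.32, 1 of 25 rose adjusted over the list alone, adjusted p = 0.00281, adjusted p = 0.384 with an estimated correlation), with HSP30 at 2.00, and PAU genes (median 0.21, 1 of 13 rose adjusted over the list alone, adjusted p = 0.0349, adjusted p = 0.187 with an estimated correlation and 0.0727 with the block by letter), with PAU7 at 0.99, were higher. With arrays centred on their medians, the heat shock, PAU, cytosolic ribosomal and reserve carbohydrate medians were -0.05, -0.21, -0.62 and 0.09. The PAU call was lost there, on the deposited values and with quantile normalization of positive values only, where the cytosolic ribosomal call was lost too (adjusted p = 0.0507). Fry called 0 of 28 lists.

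The interaction asks whether the response to overnight hypoxia depends on the genotype, and 7 genes passed. CDC19 fell with hypoxia in the wild type (-2.96) and stood at 1.31 in the arrays labelled ixr1 null, a difference of 4.27 ± 0.63 (19.3-fold, adjusted p = 0.0449). AIR2 went from -4.31 to -9.48 (-5.18 ± 0.67), MET5 from -1.35 to -6.05 (-4.70 ± 0.73, adjusted p = 0.0452) and YRB1 from -2.54 to -6.63 (-4.09 ± 0.63). EEB1 went from -4.69 to 0.35 (5.04 ± 0.66), HSL7 from -3.68 to 1.49 (5.17 ± 0.72) and SPP381 from 1.22 to 6.07 (4.85 ± 0.70). With zeros kept and values floored, AIR2 stood at -1.83 without its call, EEB1 at 2.44, HSL7 at 2.60 and YRB1 at -2.48. Each of the 7 lost its call in 13 or 14 of the 19 to 21 alternatives run on it. Of 4844 probes 4 differed upward and 3 downward, 741 had an unadjusted p under 0.05, and the median was -0.24 (-0.25 on the deposited values, -0.27 with arrays centred on their medians). The count was 0 under both of those scalings and 0 without each of the 8 arrays in turn: wild type air A or B, ixr1 null air A or B, wild type hypoxia A or B, and ixr1 null hypoxia A or B. With a block for the array letter within each condition it was also 0 in limma, with 1285 at an unadjusted p under 0.05.

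By list, the response to hypoxia was higher in the arrays labelled ixr1 null for glycolysis (median 1.39, 25 of 29 higher, 1 rose, also adjusted over the list alone, adjusted p = 9.42e-06), where the air arrays of that genotype crowded below a ceiling, and for amino acid synthesis (median 1.16, 37 of 46, 0 adjusted over the list alone, adjusted p = 3.37e-06), with ILV6 at 2.58. It was higher for wall genes (median 1.48, 14 of 18, 5 rose adjusted over the list alone, adjusted p = 0.000707), with TIP1 at 4.68, though CCW12 lay at or near the ceiling on the ixr1 null air arrays, and hexose transporters (median 2.20, 10 of 13, 2 rose adjusted over the list alone, adjusted p = 0.00112), with HXT1 at 2.85 and HXT3 at 3.69. It was lower for mitochondrial ribosomal genes (median -0.97, 59 of 70, 1 fell adjusted over the list alone, adjusted p = 0.000376), with MRPL8 at -4.04. Sulfur genes were lower (median -1.76, 1 of 23 fell, 6 fell and 2 rose adjusted over the list alone, adjusted p = 0.00273, adjusted p = 0.114 with an estimated correlation), with MET14 at -3.90. Iron regulon genes were higher (median 0.50, 2 of 23 rose adjusted over the list alone, adjusted p = 0.0124, adjusted p = 0.0611 with an estimated correlation), with FIT3 at 4.34, and oxidative stress genes lower (median -0.65, 2 of 33 fell adjusted over the list alone, adjusted p = 0.0351, adjusted p = 0.158 with an estimated correlation), with TRX2 at -5.04. Each of these 8 lists also passed fry, and under the deposited and median-centred scalings each kept its direction and its call. Hypoxic genes (median -0.04, adjusted p = 0.727) and PAU genes (median -0.03, adjusted p = 0.684) were not called, with OLE1 at 3.21 ± 0.83 (adjusted p = 0.13).

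The response to the shift showed 0 of 2178 probes past the threshold in limma, with 213 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0874 for TPO4 (4.24 ± 0.62). YCG1 (3.52 ± 0.64), ORC2, of the origin recognition complex (5.62 ± 1.08), ILV3 (8.17 ± 1.64) and FUN12, a translation initiation factor (3.04 ± 0.61), followed at adjusted p = 0.155. The median was 0.05, against -0.49 on the deposited values, -1.08 with quantile normalization of positive values only and -1.16 with arrays centred on their medians. Without wild type shift array A 12 passed and without ixr1 null shift array B 9 passed. Without both shift A arrays 6 passed and without both shift B arrays 23. With a block for the array letter within each condition 26 rose and 0 fell. Fry called 1 of 28 lists, the wall genes. Against the other probes, wall genes were higher (median 1.37, 13 of 15, adjusted p = 0.00417), with BGL2 at 2.12, as were glycolysis genes (median 0.88, 17 of 19, adjusted p = 0.0148), with TDH2 at the ceiling of the ixr1 null air arrays, and ribosome biogenesis genes (median 1.15, 6 of 7, adjusted p = 0.0204), with EBP2 at 4.18. Adjusted over the list alone, 0, 0 and 2 of their members rose. Amino acid synthesis genes (median 0.82, 30 of 35, 1 rose adjusted over the list alone, adjusted p = 0.0148, adjusted p = 0.0621 with an estimated correlation), with ILV6 at 2.17, and hexose transporters (median 1.61, 6 of 7, 0 adjusted over the list alone, adjusted p = 0.031, adjusted p = 0.0621 with an estimated correlation), with HXT1 at 1.61, were higher. Cytosolic ribosomal genes were lower (median -0.24, 71 of 101, 0 adjusted over the list alone, adjusted p = 0.0148, adjusted p = 0.567 with an estimated correlation), and without ixr1 null shift array A their median was 0.34. With arrays centred on their medians the medians of the amino acid and glycolysis lists were -0.38 and -0.02, above the -1.16 of all probes, and those of the wall, ribosome biogenesis and hexose transporter lists were 0.55, 0.36 and 0.62. The cytosolic ribosomal call was lost on the deposited values (median -0.50), with arrays centred on their medians (-1.17) and with quantile normalization of positive values only (-1.03).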

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

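Of the tests below, the one on 100 splits of the arrays was set before its result was seen, and the others, the counts among splits with 1 A and 1 B shift array on each side and among splits that part 6 pairs included, were chosen only after the result was seen. What drew attention to the results of this part was a tested difference between the genotypes in their response to low oxygen. In the response to overnight hypoxia 7 genes differed between the genotypes: AIR2 (-5.18), MET5 (-4.70) and YRB1 (-4.09) fell further in the arrays labelled ixr1 null. EEB1 (5.04), CDC19 (4.27), HSL7 (5.17) and SPP381 (4.85) went higher there. With a block for the array letter within each condition 0 passed in limma, with 1285 at an unadjusted p under 0.05. The list medians that differed were those of aerobic cell wall (1.48), glycolysis (1.39), hexose transporter (2.20), amino acid synthesis (1.16) and iron (0.50) genes, and of mitochondrial ribosome (-0.97), sulfur (-1.76) and oxidative stress (-0.65) genes. The iron, sulfur and oxidative stress calls were lost with an estimated correlation (adjusted p = 0.0611, 0.114 and 0.158). After the shift the list medians were 1.37 for wall, 0.88 for glycolysis, 0.82 for amino acid synthesis, 1.15 for ribosome biogenesis, 1.61 for hexose transporter and -0.24 for cytosolic ribosome genes, of which the amino acid, hexose transporter and cytosolic ribosome calls were lost with an estimated correlation (adjusted p = 0.0621, 0.0621 and 0.567). CCW12, TDH1, TDH2, TDH3 and FBA1, of the wall and glycolysis lists, sat at or near the ceiling of the ixr1 null air arrays.

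IXR1 was as bright in the arrays labelled ixr1 null as in the wild type. Its level would decide an exchange of the genotype labels only where it parted the genotypes. In air and after the shift the lowest of the 8 values was 3.01, above the 0.997 that was highest for LEU2, URA3 or MET17, in both genotypes. In hypoxia the lowest wild type value was 0.399, and the values of both genotypes reached into the range of those deleted genes. An exchange of labels therefore stays open in each condition. RNA from cells with an intact IXR1 in the arrays labelled null also stays open. In air 382 probes had an unadjusted p under 0.05 between genotypes where chance gives 252. With a block for the array letter within each condition 754 did, so the excess depends on the fit. In both fits 0 passed the adjusted threshold in limma, and the excess does not decide it. A probe outside the deleted part of the gene could not be tested without its sequence.

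The shift arrays A and B differed in both genotypes. Their B minus A differences correlated at 0.648 between the genotypes, across probes, which argues against noise of single arrays. Among the brightest 25% of probes the median difference was at least 2.67 times that in any other group, which argues against low signal. HSP12 and its list fell from A to B by a median of 2.33 and 2.13. A batch or a difference between cultures was not named in the labels and was not tested.

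In overnight hypoxia 203 probes moved over 16-fold on the mean of the genotypes and over 8-fold the same way in each, 77 up and 126 down, YJR018W, TDH3 and IXR1 among them. Of them 90.6% also moved over 16-fold in the deposited values, which argues against quantile normalization, and 68.2% of the probes moving that far in the wild type moved over 8-fold the same way in the arrays labelled null, against 9.02% of all probes, which argues against noise of dim spots. A different content of the spots on the hypoxia arrays may still explain them: 5 of 40 pairs of duplicated ribosomal protein genes, such as RPL27A and RPL27B, parted by over 8-fold in both genotypes, or 12.5%, against 9.94% of mismatched pairs. In the wild type shift, on other arrays, 63 of the higher and 123 of the lower probes were also measured, with medians of 0.57 and -0.94 against 4.99 and -4.99 for these in hypoxia. Yet YJR018W moved there too, from 0.333 and 0.0550 in air to 69.3 and 90.6, and TDH3 from 157 and 172 to 0.0147 and 0.0978. The medians therefore do not describe every probe, and a content of the hypoxia arrays alone would not account for these moves. The biological response to hypoxia, which the design names, stays open as well.

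For the average of the genotype over conditions, where AAD3, YDR340W and FPK1 passed, 19 of 100 splits of the arrays gave as many probes, so over these splits chance cannot be excluded. The real split gave 3 and the highest of the others 389. Of the 18 splits with more probes, 16 parted the shift arrays by letter, which points to a structure of the samples, and the highest among splits that did not was 5. Of the 67 splits with 1 A and 1 B shift array on each side, 3 gave as many as the real one, which is among them. These 3 also lie among the 31 splits that, like the real one, part all 6 pairs of arrays of the same condition and letter.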

How the results depend on the processing

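The alternatives beyond the first set, named here as the offset of positive values, the floor, positive values only, near saturation, the block within each condition, and the shift block or shift letter settings, were chosen after seeing the data. Among the named genes that passed, over the alternatives, 2541 values kept call and direction, 501 lost the call and 0 reversed. Among all probes that passed more calls were lost: 348 of 593 held in wild type hypoxia without wild type air A, and 0 of 7 in the hypoxia interaction without any 1 of its arrays. Of list calls 1111 held, 206 were lost and 6 reversed. An offset of the 10th percentile of all values, which was 0, changed nothing. Where a count moved, the cause was not tested, except that fewer probes or arrays enter by construction where some are left out.

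With values as deposited 427 probes passed in ixr1 null hypoxia against air, 25 in ixr1 null shift against air, 1 between genotypes in hypoxia, 0 in the average and 0 in the hypoxia interaction (limma, 147 and 619 at an unadjusted p under 0.05). With arrays centred on their medians these were 402, 28, 1, 0 and 0 (275 and 542 unadjusted), with 13 between genotypes after the shift. Positive values only gave 27 in ixr1 null shift, 1 between genotypes in hypoxia, and 0 and 0 in the average and hypoxia interaction (249 and 602 unadjusted). Without the dimmest 25% of probes 46 passed between genotypes in hypoxia and 24 in the hypoxia interaction. Probes with a value on all 12 arrays gave 331 in wild type hypoxia, 294 in wild type shift against hypoxia, 385 in ixr1 null hypoxia, 30 between genotypes in hypoxia and 35 in the hypoxia interaction.

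A variance trend gave 54 in wild type shift against air, 24 in ixr1 null shift, 43 between genotypes in hypoxia and 46 in the hypoxia interaction. Only the arrays of the groups compared gave 6 in wild type shift, 206 in shift against hypoxia, 11 in ixr1 null shift, 0 between genotypes in hypoxia (limma, 1069 at an unadjusted p under 0.05) and 75 in the hypoxia interaction. The offset of positive values gave 89, 23, 45 and 45 in wild type shift, ixr1 null shift, genotypes in hypoxia and hypoxia interaction. The floor gave 105, 27, 133 and 75 there, 3 between genotypes in air and 7 in the average. Leaving out probes near saturation gave 18 in wild type shift.

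Leaving out 1 array at a time, where a lone array is assumed to vary like the other groups, counts ranged from 341 to 437 in wild type hypoxia, 12 to 333 in wild type shift against air, 191 to 594 in shift against hypoxia, 389 to 519 in ixr1 null hypoxia and 8 to 126 in ixr1 null shift. Between genotypes they ranged from 0 to 0 in air, 0 to 24 in hypoxia, 0 to 14 after the shift and 0 to 1 in the average, and in the interactions from 0 to 0 (hypoxia) and 0 to 12 (shift). The median of reserve carbohydrate genes in wild type shift was -0.30 without wild type shift A and 1.90 without B. Cytosolic ribosome medians were 0.22 between genotypes after the shift and 0.34 in the shift interaction without ixr1 null shift A, and -1.01 and -0.89 without B.

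Leaving out all shift A arrays gave 123 in wild type shift, 671 in shift against hypoxia, 20 in ixr1 null shift, 18 between genotypes after the shift, 0 in the average (447 unadjusted) and 6 in the shift interaction; the reserve carbohydrate median in wild type shift was -0.30 and the cytosolic ribosome medians 0.13 and 0.26. Leaving out all shift B arrays gave 699, 839, 615, 21, 12 and 23.

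A replicate block by letter over all arrays gave 88 in ixr1 null shift, 8 between genotypes in hypoxia, and 0 and 0 in the average and hypoxia interaction (216 and 854 unadjusted). A replicate block within each condition gave 0 between genotypes in air (754 unadjusted), 1 in hypoxia, 20 after the shift, 8 in the average, 0 in the hypoxia interaction (1285 unadjusted) and 26 in the shift interaction. Of the list calls between genotypes it ended those of ATP synthase genes in hypoxia and PAU genes in the average, and no other. A replicate block in the shift arrays only gave 418 in wild type shift, 800 in shift against hypoxia, 200 in ixr1 null shift, 13 between genotypes after the shift, 13 in the average and 15 in the shift interaction.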

Other observations

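AAC3, the anaerobic ADP/ATP carrier, was singled out after its values were seen. It was listed at 0 on all 4 air arrays, which left it out of every comparison with air. It read 0.267 and 0.347 in wild type hypoxia and a mean of 1.14 in the hypoxia arrays labelled ixr1 null. In ixr1 null shift arrays it read 0.499 and 0. Between overnight hypoxia and air in the wild type, 51 probes had signal on both hypoxia arrays and 0 on both air arrays, and 27 the reverse. After the shift, 959 probes had signal on both wild type arrays and 0 on both ixr1 null arrays, and 2 the reverse. Across probes, which are not independent replicates, genotype differences correlated at -0.23 between air and hypoxia.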
